A study of Homo sapiens with 3 samples.

How the data were processed

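ATAC-seq was performed on 3 samples, 1 per group: primary human hepatocytes, 2D and 3D hepatocyte-like cells differentiated from H1 stem cells. Per the labels' protocols, libraries were amplified for a number of cycles set by quantitative PCR, size-selected on beads and sequenced as read pairs. Per the submitters' processing notes, cutadapt, Bowtie2, SAMtools, deepTools, Picard, MACS2, bedtools and HOMER were used with the hg38 genome; their versions, roles, thresholds and any shift of reads for the transposase or exclusion list are not given in the sources used here. The authors deposited 1 peak list per sample, with 4 columns: chromosome, start, end and peak name. The lists hold no height, fold, p-value or q-value, so depth and peak strength are unknown and no signal was compared. Peaks within a list did not overlap and their names were numbered without gaps. The shortest autosomal peak and the smallest gap between peaks were 168 and 169 bp in the primary list, 202 and 203 bp in the 2D list, and 124 and 125 bp in the 3D list.

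Analyses used the 22 autosomes only, because 1 sample comes from human tissue. The files held 54441, 94914 and 115772 peaks in all for primary, 2D and 3D cells. Overlaps of at least 1 bp were found with bedtools 2.31.1; other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The level of overlap by chance came from 20 circular shifts of the overlapping list along each chromosome, with the last peak end of the 3 lists as its length. Genes came from a RefSeq table of GRCh38.p14, the same assembly as hg38, with 19126 autosomal protein-coding genes plus H19, a listed non-coding gene. The table gives no strand and no transcripts, so transcription start sites, planned as the reference points, were replaced by both ends of each gene. A gene-end peak lies within 1 kb of either end, and some gene-end peaks therefore mark the 3' end of a gene or a neighbour's promoter. Peaks were assigned to the nearest gene end within 100 kb. Introns and exons could not be told apart with this table. Coordinates are 1-based on hg38.

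For counts per gene the lists were shortened to 53084 peaks each, the length of the shortest list. Without a significance column the widest peaks were kept, as planned for that case. The primary list was therefore used whole. Before the data were examined, 18 gene lists and the rule for naming genes were fixed: the 10 protein-coding genes with the largest difference in assigned peaks in each direction of each comparison, ties going to the larger covered length; members of the lists with a gene-end peak in some samples only; and CYP3A4, ALB, AFP, THRB, HNF4A and CYP7A1. A list's mean difference between 2 samples was placed among 10000 random lists of the same size, each gene drawn from the 200 nearest in rank of mean peak number. Such a percentile describes these libraries and is not a test between conditions. Neighbouring genes of a cluster are not independent draws. RXRA is in 2 lists, thyroid hormone pathway and hepatocyte transcription factors. Each autosomal list member was matched to the table, and members on the sex chromosomes were left out.

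The functions were tested on simulated data. All 19993 simulated peaks were classed correctly as overlapped or not, bedtools and array overlap calls were equal for all 91901 2D peaks, and 10 of 10 lists of 20 genes with 3 extra peaks per gene lay above the 97.5th percentile, while 6% of 200 unchanged lists fell outside the central 95%. Alternatives fixed at the same time as the gene lists were the widest 50% of each list, equal list lengths, reciprocal overlap of at least 50%, the central 200 bp of each peak, distal peaks of both lists only, full or randomly shortened lists for genes, and counting peaks within 50 kb of either gene end. Alternatives added after seeing the data were the thyroid hormone and hepatocyte transcription factor lists without RXRA, the shortening of lists at random for the overlaps, and the joining and filtering of all lists to the same shortest peak and joining gap of 202 bp. Motif content was planned but not analysed here, because it needs a genome sequence. Results for some items that the rules would name are not reported here. The other culture condition named in the series design was not analysed here.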

Results

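Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in 3 samples. These were non-cultured primary human hepatocytes, hepatocyte-like cells differentiated from pluripotent stem cells in flat (2D) culture, and hepatocyte-like cells differentiated as spheroids (3D culture). The labels mark the 3D sample S4 without explaining it. The stem cells were H1, an established human embryonic stem cell line. Each group held 1 library, so no difference between groups has a replicate check and no p-value is given. On the autosomes the authors' peak lists held 53084 peaks for primary hepatocytes, 91901 for 2D cells and 112507 for 3D cells, covering 28.4, 55.5 and 47.1 Mb. The sequencing depth of the libraries is unknown, because the lists give positions only. The lists also differed in resolution: the shortest autosomal peak was 168 bp in primary hepatocytes, 202 bp in 2D cells and 124 bp in 3D cells, and the median width was 419, 495 and 316 bp. Intervals below are 95% exact binomial (Clopper-Pearson) intervals and cover counting error only.

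The first comparison asked how much of the open chromatin of primary hepatocytes was also open in each stem cell-derived population. Of the primary peaks, 64.3% (interval 63.9 to 64.7%) were overlapped by a 3D peak and 49.96% (interval 49.5 to 50.4%) by a 2D peak. Peaks of both cultures overlapped 24496 primary peaks, 3D peaks alone overlapped 9622, 2D peaks alone 2023, and 16943 primary peaks were overlapped by neither. Circular shifts of the culture peaks along the chromosomes left overlaps averaging 3.80% (3D) and 3.64% (2D) over 20 shifts. In the reverse direction, 30.7% of 3D peaks and 28.4% of 2D peaks were overlapped by a primary peak. Between the 2 cultures, 65.0% of 2D peaks were overlapped by a 3D peak and 55.2% of 3D peaks by a 2D peak. A share depends on the length of the list that does the overlapping. With 53084 peaks drawn at random from each list, which lowers a share by about the fraction of the overlapping peaks kept, 3D peaks overlapped 31.3% of 2D peaks and 30.6% of primary peaks. The primary list stayed whole in this setting, and primary peaks still overlapped 30.5% of 3D peaks and 28.3% of 2D peaks. The size of the 3D excess over 2D depended on how the unequal lists were handled. With the widest 53084 peaks of each list, 48.0% of primary peaks were overlapped by 3D and 37.3% by 2D, whereas with random draws the shares were 30.6% and 29.0%.

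**Figure D1:**
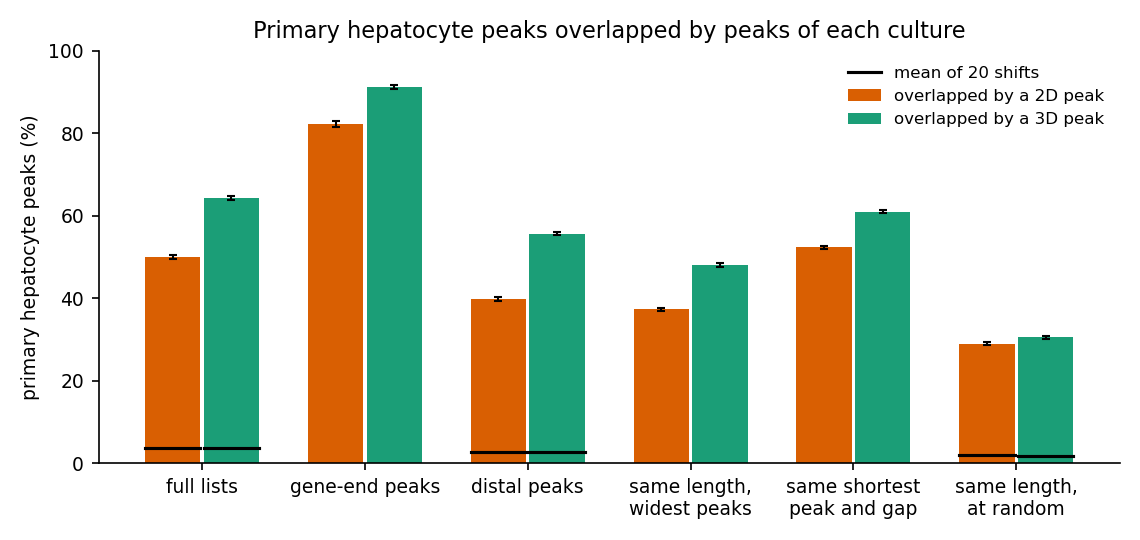
Bars give the percentage of primary hepatocyte peaks overlapped by at least 1 bp of a 2D (orange) or 3D (green) peak, for the full lists, for gene-end or distal peaks of both lists, and for 3 ways of making the lists alike; error bars are 95% exact binomial intervals and black lines the mean of 20 circular shifts where computed. The 3D bar is above the 2D bar in each pair, from 91.2% against 82.2% at gene ends to 30.6% against 29.0% for lists drawn at random to the same length.

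Overlap was higher at the ends of genes than away from them. Among primary peaks within 1 kb of either end of a protein-coding gene, 91.2% were overlapped by a gene-end 3D peak and 82.2% by a gene-end 2D peak. Among distal primary peaks, 55.7% were overlapped by a distal 3D peak and 39.9% by a distal 2D peak. Gene-end peaks made up 22.97% of the primary list (interval 22.6 to 23.3%), 14.2% of the 2D list (13.9 to 14.4%) and 14.7% of the 3D list (14.5 to 14.9%). When the 3 lists were joined into 158174 regions, 24079 held a peak of every list, and 41.2% of these lay at a gene end. Regions shared by primary and 3D cells only numbered 9380, those shared by primary and 2D cells only 1669. The 30360 regions found in 2D cells only lay a median of 82.1 kb from the nearest gene end and 2.16% of them were gene-end regions, while the 40584 regions found in 3D cells only lay 27.6 kb away (6.43% at gene ends).

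Genes of mature hepatocyte function separated the 3 samples. Over the 126 genes of 6 hepatocyte lists (plasma proteins, cytochrome P450 enzymes, other drug metabolism, bile acids and transport, urea cycle with amino acid and glucose metabolism, and hepatocyte transcription factors), 114 (90.5%) had a gene-end peak in primary hepatocytes, 99 (78.6%) in 3D cells and 72 (57.1%) in 2D cells. Among the 19001 other genes the order was different, with 63.1% in primary hepatocytes, 75.3% in 3D cells and 68.7% in 2D cells. All 18 housekeeping control genes had a gene-end peak in primary and 3D cells, and 17 of them in 2D cells.

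The comparison of 2D cells with primary hepatocytes showed fewer gene-end peaks at hepatocyte genes in 2D cells. Of 17 cytochrome P450 drug metabolism genes, 15 had a gene-end peak in primary hepatocytes and 5 in 2D cells. CYP2C8, which oxidizes many drugs, CYP2E1, the ethanol-inducible enzyme, and CYP1A2, which metabolizes caffeine, had a gene-end peak in primary hepatocytes and none in 2D cells. Plasma protein genes had a gene-end peak in 25 of 27 cases in primary hepatocytes and 17 in 2D cells; C3, the central complement component, had 8 assigned peaks in the primary list and none in the 2D list. For bile acid and transport genes the numbers were 18 and 10 of 20, and CYP7A1, the rate-limiting enzyme of bile acid synthesis, BAAT, which conjugates bile acids, and ABCB11, the bile salt export pump, were among those without one in 2D cells. The primary peak at CYP7A1 was 199 bp wide, below the shortest 2D peak of 202 bp. For the urea cycle, amino acid and glucose genes they were 20 and 15 of 22, with ARG1, the last enzyme of the urea cycle, and SDS, serine dehydratase, among those without one in 2D cells. For the other drug metabolism genes they were 17 and 10 of 21, with the alcohol dehydrogenase ADH1B at 5 assigned peaks in the primary list and none in the 2D list. All 19 hepatocyte transcription factors had a gene-end peak in primary hepatocytes and 15 in 2D cells. Those without one in 2D cells were PROX1, NR1I2 (the xenobiotic receptor PXR), NR1H4 (the bile acid receptor FXR) and RXRA.

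In lists of equal length, the mean number of peaks assigned to the nearest gene end within 100 kb was lower in 2D cells than in primary hepatocytes for each of these lists. Hepatocyte transcription factors had 2.26 peaks per gene in 2D cells and 9.53 in primary hepatocytes, and cytochrome P450 genes 0.824 and 4.47, with all 17 of the latter lower in 2D cells. In the full lists 2D cells had 5.37 peaks per transcription factor gene and 1.94 per cytochrome P450 gene, with 15 of the latter lower and 2 higher than in primary hepatocytes. Each of the 6 lists lay at or below percentile 0.315 of 10000 random lists matched on peak number. The acute phase and oncostatin M list (percentile 1.04; 1.78 peaks per gene in 2D cells and 4.00 in primary hepatocytes) and the thyroid hormone pathway list (percentile 0.005; 2.16 and 6.16) also lay in the lower tail. RXRA carried much of the thyroid list: without it, the values were 2.28 and 4.44 (percentile 1.295). In the thyroid list, 14 genes had a gene-end peak in 2D cells and 18 of 19 in primary hepatocytes. With peaks counted within 50 kb of either gene end, the bile acid and transport list moved to percentile 7.52.

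The single genes with the largest differences were named by a rule of size. RXRA, the retinoid X receptor that pairs with many nuclear receptors including those for thyroid hormone, had 37 assigned peaks in primary hepatocytes and none in 2D cells (5 in the full 2D list). The transcription factor gene NFIC had 22 and 1, the gene of the lipoprotein receptor SCARB1 23 and 4, GADD45G 25 and 6, SEPTIN9 22 and 0, CLMN 19 and 0, IQSEC1 22 and 3, KIAA1671 21 and 2, and ARHGEF10L 20 and 1. The 2D values were larger in the full 2D list for all of these but NFIC (1). There SEPTIN9 had 10 peaks, CLMN 5, SCARB1 10, GADD45G 10, IQSEC1 7, KIAA1671 6 and ARHGEF10L 4. In the other direction, ANGPT1, which encodes a ligand of the endothelial receptor TEK, had 17 peaks in 2D cells and none in primary hepatocytes. BMPER, encoding a secreted regulator of bone morphogenetic proteins, had 18 and 2, and CFTR, encoding a chloride channel of epithelia such as bile ducts, 18 and 3. STXBP6 had 22 and 6, NAV3 17 and 1, KCTD8 15 and 1, ATP10B 14 and 0, TAFA4 14 and 0, RASEF 17 and 4, and ZNF91 15 and 1. ZNF91 belongs to a family of closely related zinc finger genes, whose reads can be shared between copies. All of these genes kept their direction in the full lists and with peaks counted within 50 kb of either gene end.

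The comparison of 3D cells with primary hepatocytes showed fewer missing gene-end peaks at hepatocyte genes, and more peaks at fetal liver and bile duct genes. Gene-end peaks were found in 3D cells at 26 of 27 plasma protein genes, 10 of 17 cytochrome P450 genes, 13 of 21 other drug metabolism genes, 14 of 20 bile acid and transport genes, 18 of 22 urea cycle, amino acid and glucose genes, and 18 of 19 hepatocyte transcription factors. CYP1A2, CYP2B6, CYP2C8, CYP2E1 and CYP4F2 had one in primary hepatocytes and in neither culture. The same held for HAMP, which encodes the iron hormone hepcidin, and for SAA1 and SAA4 among the acute phase genes. Of 14 fetal liver genes, 10 had a gene-end peak in 3D cells and 5 in primary hepatocytes; AFP, the fetal serum protein, EPCAM, a surface marker of hepatic progenitors, and IGF2BP1 and IGF2BP3, which encode fetal RNA-binding proteins, had one in 3D cells only of this pair. The AFP peak lay at the upper end of the gene only, and no sample had a peak within 1 kb of its lower end. Of 12 cholangiocyte genes, 11 had one in 3D cells and 5 in primary hepatocytes, with KRT7, KRT19 and SOX9, markers of bile duct cells, among those in 3D cells and not in primary hepatocytes. The fetal liver and cholangiocyte counts come from lists of unequal length. Over all 19127 genes, 75.3% had a gene-end peak in 3D cells and 63.3% in primary hepatocytes, against 71.4% and 35.7% of the fetal liver genes.

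By peaks per gene in lists of equal length, the same 6 hepatocyte lists lay at or below percentile 0.175 in 3D minus primary. Cytochrome P450 genes had 2.29 peaks per gene in 3D cells and 4.47 in primary hepatocytes, hepatocyte transcription factors 6.37 and 9.53, and thyroid hormone pathway genes 3.95 and 6.16 (percentile 0.03). The lower 3D values depended on the equal length of the lists. In the full lists, where the 3D list is the longest, 3D cells had 11.4 peaks per transcription factor gene against 9.53 in primary hepatocytes, 7.58 against 6.16 per thyroid hormone pathway gene, 5.22 against 4.48 per plasma protein gene, 5.15 against 4.15 per bile acid and transport gene, 5.64 against 5.55 per urea cycle, amino acid and glucose gene, and 4.18 against 4.47 per cytochrome P450 gene. Relative to random lists matched on peak number, these lists stayed at or below percentile 0.11 there. Without RXRA, at equal length, the thyroid list moved to percentile 3.78, inside the central 95% of matched lists, and the transcription factors had 6.06 and 8 peaks per gene (percentile 1.395). The fetal liver list lay at percentile 100, with 4.86 peaks per gene in 3D cells and 1.93 in primary hepatocytes and 11 of 14 genes higher in 3D cells. The cholangiocyte list (percentile 98.9; 5.75 and 3.67) and the early endoderm and gut list (percentile 97.7; 4.50 and 3.00) were also in the upper tail, but moved to percentiles 91.4 and 77.4 when the lists were shortened at random instead of by width.

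RXRA again led the genes with more peaks in primary hepatocytes (37, against 12 in 3D cells), followed by NFIC (22 and 2), SCARB1 (23 and 8), SH3RF1 (20 and 5), TTC34 (25 and 12), KIAA1671 (21 and 8), IQSEC1 (22 and 9), MICAL3 (21 and 8) and ANO1 (17 and 4). Much of the size of these differences came from the equal length of the lists. In the full lists the primary and 3D values were 37 and 19 for RXRA and 22 and 7 for NFIC, but 23 and 21 for SCARB1, 20 and 19 for SH3RF1, 25 and 22 for TTC34, 21 and 16 for KIAA1671, 22 and 18 for IQSEC1 and 21 and 18 for MICAL3, and ANO1 was reversed (17 and 18). Genes with more peaks in 3D cells were led by GULP1 (16, against 1), ATP10A (15 and 1), RBPJ, the nuclear effector of Notch signalling (17 and 4), and YWHAZ (16 and 4). Others were F3, which encodes the coagulation initiator tissue factor (13 and 1), PARM1 (12 and 0), ARHGAP5 (15 and 4), LIFR, a receptor subunit for leukaemia inhibitory factor and oncostatin M (13 and 2), UNC13C (11 and 0), and LOC124904660 on chromosome 19 (11 and 0).

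**Figure D2:**
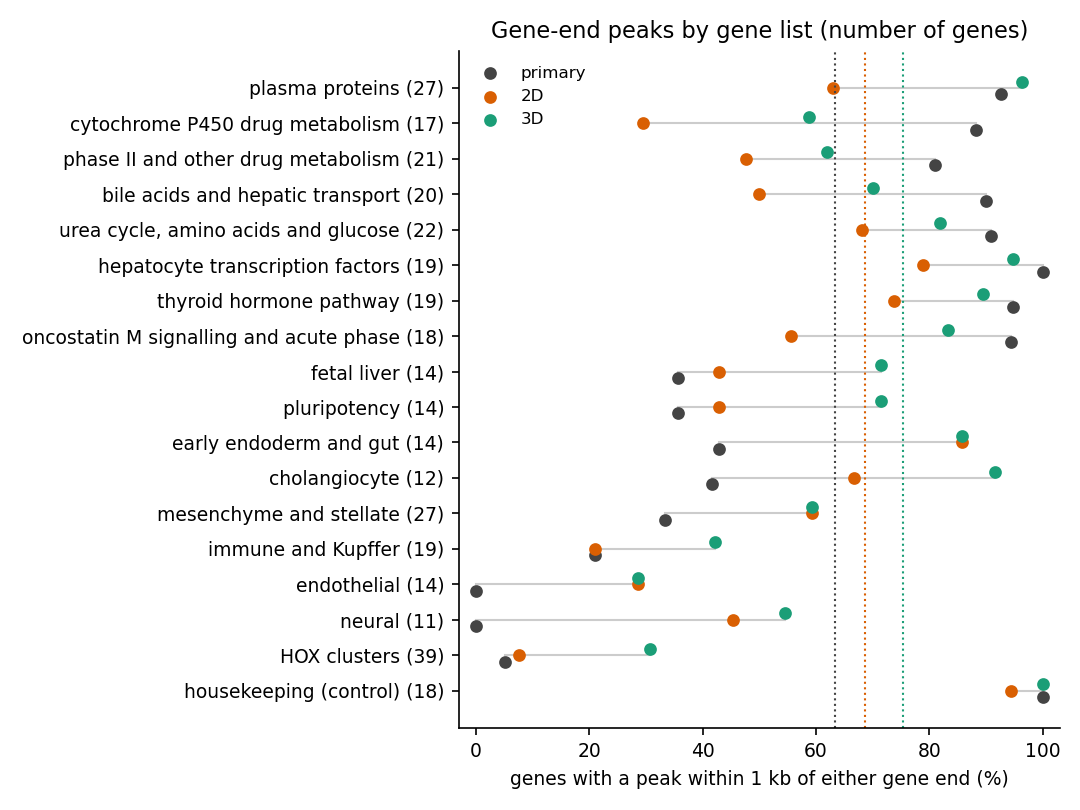
Each row is a gene list with its number of genes; points give the percentage of its genes with a peak within 1 kb of either gene end in primary hepatocytes (grey), 2D cells (orange) and 3D cells (green), and dotted lines the same percentage over all 19127 genes. For cytochrome P450 genes the points are at 88.2% in primary hepatocytes, 58.8% in 3D cells and 29.4% in 2D cells, whereas housekeeping genes are at 94.4% or more in each sample.

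The comparison of 3D with 2D cells asked how the spheroids differed from the flat culture at these genes. Gene-end peaks present in primary and 3D cells and absent from 2D cells were found at 8 plasma protein genes, 5 cytochrome P450 genes, 4 other drug metabolism genes, 4 bile acid and transport genes, 3 urea cycle, amino acid and glucose genes and 3 hepatocyte transcription factors. They included SERPINA1 (alpha-1 antitrypsin), APOC3 (an apolipoprotein), CYP3A4, which oxidizes more drugs than most other liver enzymes, CYP7A1, ABCB11, G6PC1, the terminal enzyme of glucose release, PROX1 and NR1I2. At SERPINA1, primary hepatocytes had a peak at both ends of the gene and 3D cells at the lower end only. The CYP7A1 peaks were 199 bp (primary) and 163 bp (3D) wide, below the shortest 2D peak of 202 bp. The opposite pattern, a gene-end peak in primary and 2D cells but not in 3D cells, was found at 1 gene of these lists, UGT2B10, which encodes a glucuronosyltransferase and has closely related neighbours. These counts come from the full lists, of which the 3D list is the longest, and other genes leaned the same way. Of 11681 other genes with a gene-end peak in primary and 3D cells, 11016 had one in 2D cells. Of 11053 with one in primary and 2D cells, 11016 had one in 3D cells.

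In lists of equal length, hepatocyte transcription factors had 6.37 peaks per gene in 3D cells and 2.26 in 2D cells (17 of 19 genes higher in 3D cells, percentile 100), cytochrome P450 genes 2.29 and 0.824 (percentile 98.8), the thyroid hormone pathway 3.95 and 2.16 (percentile 98.0), and the oncostatin M and acute phase list 3.44 and 1.78 (percentile 97.7). With lists shortened at random these 4 lists lay at percentiles 93.3, 96.7, 93.8 and 74.0, inside the central 95% of matched lists, and the thyroid list lay at 91.4 without RXRA. The fetal liver list (4.86 and 2.64, percentile 99.8) stayed in the upper tail under each alternative. The mesenchyme and stellate list lay in the lower tail (2.56 peaks per gene in 3D cells and 2.93 in 2D cells, percentile 2.21), but the sign of its mean difference did not hold. 3D cells had the higher mean in the full lists (5.04 and 4.96, percentile 0.515), with lists shortened at random (2.48 and 2.33, percentile 36.3) and within 50 kb of either gene end (3.70 and 3.59, percentile 3.165). The plasma protein, other drug metabolism, bile acid and urea cycle lists lay between percentiles 63.8 and 87.8. The housekeeping control list lay above these, at 93.5 (3.00 peaks per gene in 3D cells and 1.83 in 2D cells). With lists shortened at random it lay at 94.2, above the transcription factor, thyroid and oncostatin M lists. In that setting the 3D excess was therefore not particular to those lists. Over the 3 comparisons, 26 of 54 list differences lay outside the central 95% of matched lists, and 16 did so under all 3 alternatives. By chance 2.7 would be outside if genes were independent draws. Neighbouring genes of a cluster are not, RXRA is in 2 lists and the 3 comparisons share samples. The 26 are therefore not separate outcomes to weigh against 2.7.

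Genes with more peaks in 3D than in 2D cells were RHOU (20 and 4), SEPTIN9 (15 and 0), ZMIZ1 (18 and 4), ETS2 (15 and 2), PDE9A (14 and 2), RIPK4 (14 and 2), RXRA (12 and 0), ZBTB16 (19 and 8), CPEB4 (14 and 3) and the corepressor gene TLE3 (14 and 3). Each of these 10 also had at least 7 assigned peaks in primary hepatocytes. Genes with more peaks in 2D cells were NAV3 (17 and 3), FREM2 (16 and 3), KYNU, an enzyme of tryptophan breakdown (17 and 6), KCTD8 (15 and 4), the synaptotagmin gene SYT1 (15 and 4), KIF21A (14 and 3), PRIM2 (11 and 0), TAFA4 (14 and 4), CHRM3, a muscarinic acetylcholine receptor (15 and 5), and STPG2 (13 and 3). These 10 had at most 5 assigned peaks in primary hepatocytes. CHRM3 had 19 peaks in both cultures in the full lists, and the other 19 genes kept their direction there. The values of 0 were not found in the full lists. In 3D and 2D cells SEPTIN9 had 29 and 10 peaks there and RXRA 19 and 5, and in 2D and 3D cells PRIM2 had 17 and 2.

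**Figure D3:**
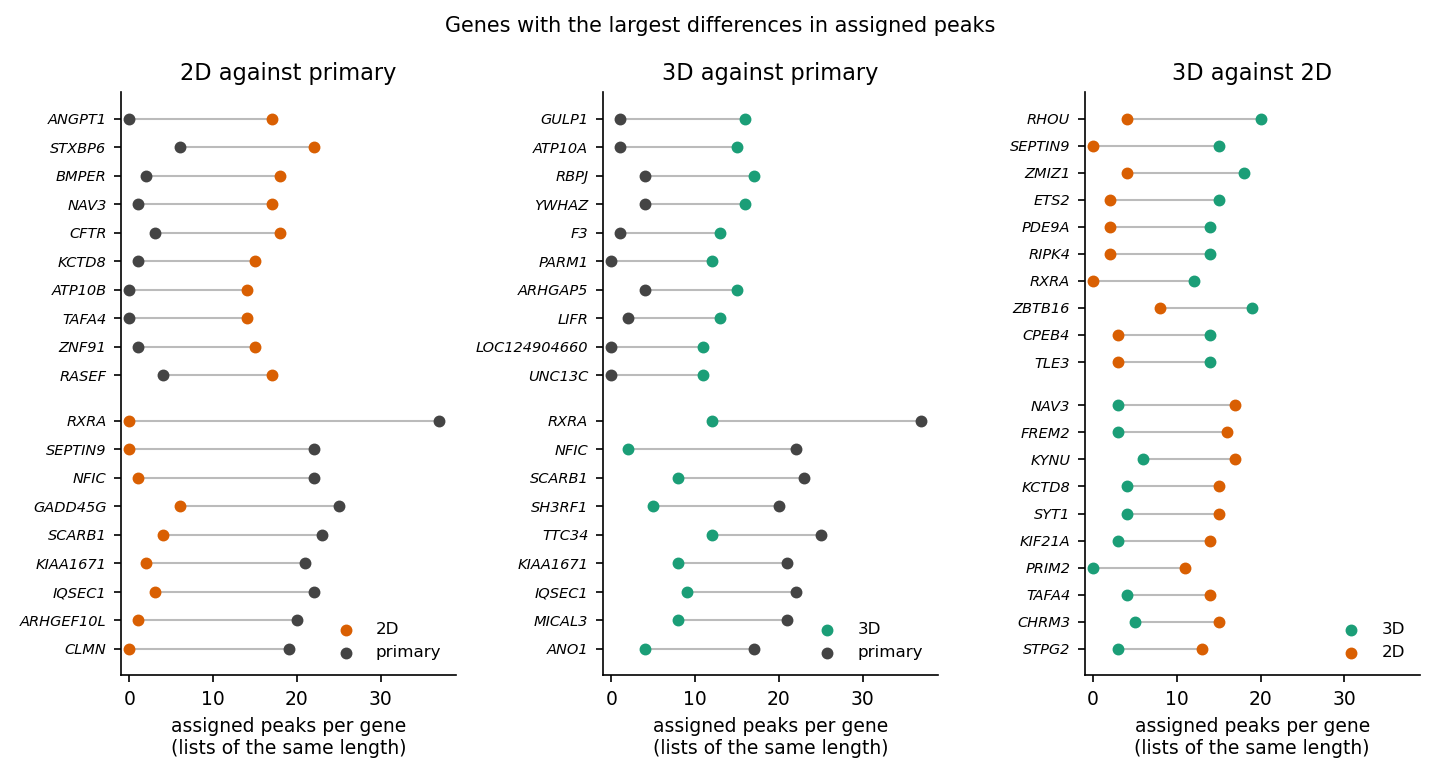
For each pair of samples, points give the number of peaks assigned to a gene (nearest gene end within 100 kb, lists of equal length) for the named genes, up to 10 in each direction; grey is primary hepatocytes, orange 2D cells and green 3D cells. RXRA, with 37 peaks in primary hepatocytes, 12 in 3D cells and none in 2D cells, is plotted in all 3 comparisons.

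At CYP3A4 (chromosome 7, 99756967 to 99784184, hg38), which is transcribed from its upper coordinate, a peak covered the start of the gene in primary hepatocytes (99783996 to 99784389), a peak lay beside it in 3D cells (99784207 to 99784469), and 2D cells had none there. Upstream, a peak at 99794787 to 99795440 in primary hepatocytes was matched by one at 99794840 to 99795375 in 3D cells. A further primary peak at 99791778 to 99792300 had no counterpart in either culture. Within 25 kb of the gene the full lists held 5 peaks in primary hepatocytes, 2 in 2D cells and 12 in 3D cells. A 3D peak among these (99735167 to 99735409) covered the upper end of the neighbouring gene CYP3A7 (99735196). In lists of equal length, 4, 1 and 5 peaks were assigned to CYP3A4 in primary, 2D and 3D cells. At ALB, the serum albumin gene (chromosome 4, 73404287 to 73421482), the peak over the start of the gene (73404022 to 73404388) was found in primary hepatocytes and in neither culture, while all 3 samples had a peak before it, at 73397106 to 73398106 in primary hepatocytes, 73397139 to 73397972 in 2D cells and 73396859 to 73397701 in 3D cells. In both cultures ALB counted as a gene with a gene-end peak through its upper end only. The neighbouring AFP gene (73436221 to 73456174) had 1 peak inside it in primary hepatocytes, 5 in 2D cells and 6 in 3D cells, and a wide peak just beyond its upper end was present in 2D cells (73456294 to 73459055) and 3D cells (73456251 to 73459265) only. No sample had a peak within 1 kb of the lower end of AFP.

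**Figure D4:**
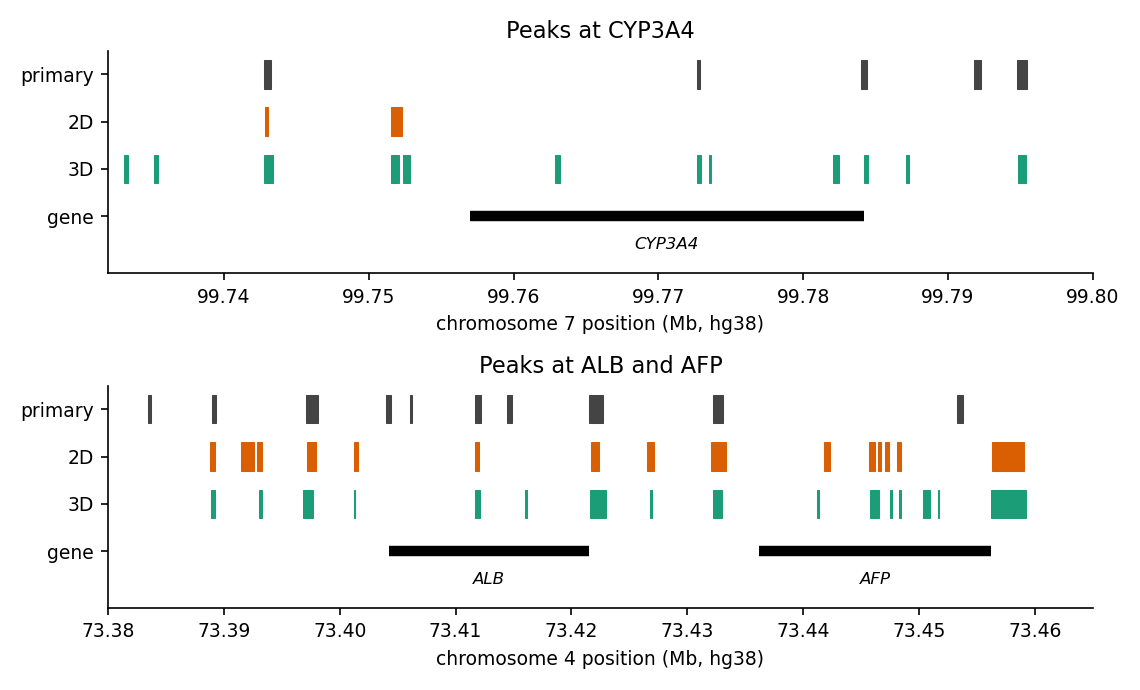
Boxes mark the authors' peaks to scale along the CYP3A4 region of chromosome 7 and the ALB and AFP region of chromosome 4 (position in Mb, hg38) in primary hepatocytes, 2D cells and 3D cells; black bars are the genes. Within 25 kb of CYP3A4 the full lists, which differ in length, hold 5 primary, 2 2D and 12 3D peaks, and the peak over the start of ALB is in the primary row alone.

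At CYP7A1 (chromosome 8, 58490178 to 58500163), a peak beside the upper end, where transcription starts, was found in primary hepatocytes (58500191 to 58500389) and 3D cells (58500199 to 58500361) and not in 2D cells. These peaks were 199 bp (primary) and 163 bp (3D) wide. The shortest 2D peak was 202 bp, so the 2D list could not hold a peak of either width, and its absence there does not separate the samples. HNF4A, a central hepatocyte transcription factor (chromosome 20, 44355699 to 44434596), had 12 peaks inside the gene in primary hepatocytes, 6 in 2D cells and 13 in 3D cells in the full lists. THRB, the thyroid hormone receptor beta gene (chromosome 3, 24117153 to 24495708), had a gene-end peak in every sample and 16, 28 and 26 peaks inside the gene in primary, 2D and 3D cells in the full lists. In lists of equal length the assigned peaks, a different count, were 16, 4 and 10 for HNF4A and 13, 12 and 11 for THRB. In the full lists the assigned peaks were 16, 6 and 15 for HNF4A and 13, 21 and 24 for THRB. The order of the samples at THRB thus depended on list length.

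Markers of other cell types and of earlier stages were compared in the same way. Of 14 early endoderm and gut genes, 12 had a gene-end peak in each culture and 6 in primary hepatocytes; SOX17, GATA4, EOMES, CXCR4 and PDX1 had one in both cultures only. Of 27 mesenchyme and stellate genes, 16 had one in each culture and 9 in primary hepatocytes. Of 14 endothelial genes, 4 had one in each culture and none in primary hepatocytes, and of 11 neural genes, 5 had one in 2D cells, 6 in 3D cells and none in primary hepatocytes. Pluripotency genes had one in 5 of 14 cases in primary hepatocytes, 6 in 2D cells and 10 in 3D cells, while POU5F1, the core pluripotency factor, had none in any sample. Of 19 immune and Kupffer cell genes, 4 had one in primary hepatocytes, 4 in 2D cells and 8 in 3D cells. HOX cluster genes had one in 2, 3 and 12 of 39 cases. These counts come from lists of unequal length. At equal length the pluripotency list had 1.29 peaks per gene in 3D cells and 1.5 in primary hepatocytes (percentile 24.0; 1.86 and 1.5, percentile 82.2, with lists shortened at random). The immune (1.79 and 1.21, percentile 92.8), endothelial (2.00 and 1.43, percentile 84.7) and neural lists (2.09 and 1.27, percentile 92.1) also lay inside the central 95% in 3D minus primary, as all 4 lists did in 2D minus primary (percentiles 50.3 to 78.8). The endothelial list moved to percentile 98.6 in 3D minus primary with full lists. In peaks per gene, 2D minus primary placed the mesenchyme and stellate list at percentile 99.3 and the HOX list at 2.295, but at 90.5 and 18.2 with lists shortened at random. Cholangiocyte genes had gene-end peaks at 5 of 12 genes in primary hepatocytes, 8 in 2D cells and 11 in 3D cells.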

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

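The joined and filtered lists, the random shortening for overlaps and the lists without RXRA were chosen after seeing the data. No paired analysis was possible because each group holds 1 library, and for the same reason no replicate was left out. In every overlap alternative, 3D peaks overlapped more primary peaks than 2D peaks did. Shares of primary peaks overlapped by 2D and by 3D were 51.7% and 67.6% with the widest 50% of each list (26542, 45950 and 56253 primary, 2D and 3D peaks), 37.3% and 48.0% with the widest peaks at equal length, 34.2% and 48.5% with reciprocal overlap, 38.1% and 55.3% with central 200 bp windows, 39.9% and 55.7% with distal peaks of both lists, 52.3% and 61.0% with the same shortest peak and joining gap, and 29.0% and 30.6% with random shortening. In the same order of settings, primary peaks overlapped 29.6% of 2D and 32.3% of 3D peaks, then 36.03% and 47.7%, 19.8% and 22.9%, 22.03% and 26.1%, 20.3% and 24.1%, 27.0% and 35.3%, and, with random shortening, 28.3% and 30.5%. 3D peaks overlapped 60.1%, 55.9%, 44.4%, 55.4%, 59.9%, 56.7% and, with random shortening, 31.3% of 2D peaks. Primary peaks overlapped by 3D only and 2D only numbered 5146 and 935 in the widest 50%, and 9526 and 8687 with random shortening; the fall of the overlaps there follows from the smaller lists, since the full shares times the fraction of peaks kept come to 28.9% and 30.3%. What depth limits cannot be given, since the lists carry no counts. Motif content and its alternatives were not run, because they need a genome sequence.

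For the gene lists, no percentile outside the central 95% crossed to the other side of the median, and 16 of 26 stayed outside under all 3 alternatives fixed in advance (7 of 10 for 2D minus primary, 8 of 10 for 3D minus primary, 1 of 6 for 3D minus 2D). The mean differences themselves were less stable. With full lists, 5 of the 10 in 3D minus primary changed sign: hepatocyte transcription factors from -3.16 to 1.89 peaks per gene, thyroid hormone from -2.21 to 1.42, plasma proteins from -1.59 to 0.741, bile acids from -1.5 to 1, and the urea cycle list from -2.41 to 0.0909. Mesenchyme in 3D minus 2D changed from -0.37 to 0.0741 with full lists, 0.148 with random shortening and 0.111 within 50 kb. None of the 10 in 2D minus primary changed sign under these alternatives. Without RXRA, thyroid hormone came inside at 3.78 (3D minus primary) and 91.4 (3D minus 2D). With full lists the percentiles that came inside were HOX at 15.4 (2D minus primary), early endoderm at 91.7 (3D minus primary), and in 3D minus 2D cytochrome P450 at 91.3, thyroid hormone at 96.7 and oncostatin M at 70.6. Those that went outside were oncostatin M at 0.675 and endothelial at 98.6 (3D minus primary) and HOX at 99.4 (3D minus 2D). With random shortening, mesenchyme came inside at 90.5 and HOX at 18.2 (2D minus primary), early endoderm at 77.4 and cholangiocyte at 91.4 (3D minus primary), and in 3D minus 2D cytochrome P450 at 96.7, hepatocyte transcription factors at 93.3, thyroid hormone at 93.8, oncostatin M at 74.0 and mesenchyme at 36.3, while oncostatin M at 1.78 and HOX at 99.5 (3D minus primary) and HOX at 100 (3D minus 2D) went outside. Within 50 kb of either gene end, bile acids came inside at 7.52 (2D minus primary), and in 3D minus 2D cytochrome P450 at 96.1, hepatocyte transcription factors at 87.9, thyroid hormone at 77.5 and mesenchyme at 3.16; early endoderm at 98.6 (2D minus primary), oncostatin M at 0 and HOX at 1.435 (3D minus primary) and HOX at 100 (3D minus 2D) went outside. HOX in 3D minus primary thus lay at 28.4 as reported, and in opposite tails under random shortening and the 50 kb window, so no direction is given for it. The cause of these changes was not tested. Of each 10 named genes, 9 or 10 kept their direction under both alternatives, but between 1 and 5 were again among the 10 in the sets that changed most.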

Other observations

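The comparison of gene families, the trend across chromosomes, both tests on hepatocyte gene ends, the test of list length and the genes CD163 and CD14 were chosen after the values they rest on had been seen, as were the lists with the same shortest peak and joining gap and the random shortening. Families of at least 20 autosomal protein-coding genes that share a symbol stem (95 in all, grouped by spelling and not by function) were compared by gene-end peaks in the full lists, where all 19127 genes had one in 63.3% of cases in primary hepatocytes, 68.6% in 2D cells and 75.3% in 3D cells. Keratin genes (KRT, 55 genes) had one at 4 genes in primary hepatocytes, 4 in 2D cells and 15 in 3D cells. Cadherin genes (CDH, 23 genes), which encode cell adhesion proteins, had one at 5, 16 and 16 genes in the same order. Collagen and related COL genes (42 genes) had one at 9, 24 and 31 genes, and chemokine genes (CCL, 28 genes) at 7, 1 and 12. Zinc finger genes (ZNF, 505 genes) had one at 370, 436 and 445 genes, and olfactory receptor genes (OR, 391 genes) at 7, 27 and 20. Peaks per gene in lists of equal length changed the order for CCL (1.11 in primary hepatocytes, 0.429 in 2D cells and 0.75 in 3D cells) and COL (2.26, 3.05 and 2.81). The order was the same for OR (0.166, 0.348 and 0.220) and ZNF (1.54, 1.86 and 1.90). CDH and KRT, which had ties in gene-end counts, had 2.09, 4.61 and 3.57, and 0.455, 0.2 and 0.745. List length and measure both differ between the 2 counts, so the changes cannot be put down to either. Genes of these families lie in clusters and are not independent, and reads of near-identical members can be shared.

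The 2D list was sparse on gene-rich chromosomes. The ratio of 2D to 3D peaks was 1.04 on chromosome 4, with 4.05 protein-coding genes per Mb, and 0.516 on chromosome 17, with 14.0. Across the 22 autosomes, which are not independent replicates, Spearman's rho of this ratio with gene density was -0.85 (-0.84 without chromosome 19), and -0.84 for distal peaks alone. The ratio of primary to 3D peaks went the other way, with rho 0.70 (0.65 without chromosome 19). GC content was not tested, since no genome sequence was used here. The 1669 regions shared by primary and 2D cells only lay a median of 195.6 kb from the nearest gene end, against 15.7 kb for the 9380 shared by primary and 3D cells only.

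More primary peaks were overlapped by 3D than by 2D peaks, with 4.76 primary peaks in 3D only for each in 2D only. Whether list length is the cause was not settled by shortening the lists. Over 20 random draws the ratio was 1.06 to 1.12 (mean 1.11). A bound, above 1.1, was set in advance for random draws. The mean met it, but not each draw did, and the requirement that each way of shortening meet it was added afterwards. With the widest 53084 peaks of each list the ratio was 3.11. However, random draws split shared peaks between the cultures, and the widest peaks are a smaller part of the 3D (47.2%) than of the 2D list (57.8%). With the same shortest peak and joining gap the ratio was 2.62, which argues against peak resolution as the whole cause; this removed narrow 3D peaks (82678 remained) but none of the 91901 2D peaks, so it does not settle list length. The ratio was 2.81 on the 5 gene-poorest chromosomes and between 2.07 and 13.8 on each of the 22, which argues against the scarcity of 2D peaks on gene-rich chromosomes as the whole cause. Only chromosomes 4 and 13 held more 2D than 3D peaks (6409 and 6142 on chromosome 4, 3070 and 3043 on chromosome 13). Their ratios were 3.19 and 3, which argues against a longer 3D list as the whole cause on those chromosomes. That comparison was chosen after the values had been seen. List length on the other chromosomes, depth, library quality, culture format and GC bias remain open, since each group holds 1 library.

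Hepatocyte genes with a gene-end peak in primary and 3D cells lacked one in 2D cells more often than other genes did. Of 93 hepatocyte-list genes with a gene-end peak in primary and 3D cells, 66 (71.0%, interval 60.6 to 79.9%) had one in 2D cells, against 94.3% of 11681 other genes. A 2D list missing gene ends alike at all genes would not give this gap of 23.3 percentage points. Peak strength is unknown and was not matched, so the gap cannot speak to a 2D list that misses weaker gene ends. In lists of other genes matched on the width of the gene-end peak, the median was 94.6% when matched in primary cells and 83.9% when matched in 3D cells, and the hepatocyte share lay at percentile 0 of both (the lowest of 10000 lists being 84.9% and 72.0%), which argues against lower sensitivity for short peaks as the whole cause; the lower median under 3D matching shows that peak width goes with part of the gap. In the reverse direction 66 of 67 hepatocyte genes with a gene-end peak in primary and 2D cells had one in 3D cells (98.5%, against 99.7% of other genes). Nearly all genes reach this share in the longer 3D list, so the reverse direction cannot tell hepatocyte genes from others. A candidate explanation is a less complete opening of chromatin at hepatocyte gene ends in flat culture, which 1 library per group cannot separate from the quality of the 2D library. Promoters were not measured as such, because a gene-end peak can lie at either end of a gene.

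A further hypothesis was that immune cells among the primary hepatocytes would add peaks at immune and Kupffer genes to the primary list. In primary minus 3D the immune list lay at percentile 7.155 of matched lists, and at 43.975 with lists shortened at random, both below the bound of 90 set in advance against such an excess. The bound does not decide, because the 19 genes went both ways (3 with more peaks in primary hepatocytes, 6 with more in 3D cells, 10 equal) and had few peaks (1.21 per gene in primary hepatocytes). CD163 (4 peaks in primary hepatocytes, 0 in 2D and 1 in 3D cells) and CD14 (3, 1 and 0), both genes of Kupffer cells and monocytes, were higher in primary hepatocytes. PTPRC, the common leukocyte gene, was lower there (1, 6 and 4). In the full lists CD163 had 4, 2 and 3 peaks, CD14 3, 1 and 0, and PTPRC 1, 18 and 8. Neither CD163 nor PTPRC had a gene-end peak in any sample. CD14 had one at both ends of the gene in primary hepatocytes and none in either culture. It was the only gene of the list with one in primary hepatocytes alone, while 3 genes had one in 3D cells alone. A share of immune or Kupffer cells in the primary hepatocytes could explain some of the primary peaks at immune genes and stays open.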
